A study of Homo sapiens with 26 samples.

How the data were processed

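Total RNA of 26 cultured lines was measured on 1-colour Affymetrix expression arrays with biotin-labelled cRNA, 1 array per line, per the labels' protocols. All lines descend from MDA-MB-231, an established human triple-negative breast cancer cell line. Each line was placed in 1 of 9 groups by its title: the parental line, 5 bone-metastatic, 5 lung-metastatic and 6 weakly metastatic lines, the fusion partners Bm and Lm, the self-fused lines BBm and LLm, and 5 hetero-fused lines. Replicate numbers within a group were given in accession order and pair no samples.

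The deposited table held 22283 probe sets as a linear ratio per array, from 0.00234 to 806. The software, background correction and array scaling that the authors used are not given in the sources used here, and the direction of the ratio was taken from the values, a higher ratio standing for a higher signal on that array. The scale of the authors' signals is not given either, and it was inferred from the values, as was the centring. The median deposited ratio was 0.982 for the parental line, 0.958 for Bm, 0.945 for Lm, 0.941 for BBm and 0.962 for LLm. Among the hetero-fused lines it was 0.958 for BLm-DRUG, 0.966 for BLm-FACS, and 0.962, 0.942 and 0.955 for clones 8, 12 and 18. It was 0.998, 1.01, 1.03, 1.01 and 1.11 for the bone lines 1833, SCP14, SCP20, SCP25 and SCP46. It was 0.991, 0.990, 0.979, 0.998 and 0.962 for the lung lines 3481, 4142, 4173, 4175 and 4180. It was 1.05, 1.00, 1.05, 1.03, 1.05 and 1.03 for the weak lines SCP43, SCP32, SCP28, SCP6, SCP4 and SCP3. In 20849 probe sets the median over the 26 arrays was 1, so the deposited ratio was centred per probe set. The other 1434 probe sets had lower medians and appeared to be divided by a fixed floor.

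The signal behind each deposited ratio was recovered from the spacing of the values. The ratios of every probe set were whole multiples of a signal step of 0.1 after a divisor per probe set and a factor per array, within a tolerance of 0.08 of a step for 100% of the values. The divisors of all 22283 probe sets were found by a search of up to 400000 steps. The recovered signals of each array had a trimmed mean, without the 2% at each end, of 500.15 to 500.21 and a median of 115 to 169. In the deposited ratios each array had been divided by a factor that equals its median. The values used here are the recovered signals with each array brought to a median of 142, as log2(signal + 16). A change is therefore on the log2(value + 16) scale, which understates the change of genes with a low signal. Levels below are on this scale unless a signal is named. The design written beforehand chose 1 probe set per gene by mean level and filtered on level, except for a table centred per probe set, where it took the probe set with the largest SD and no filter. Because levels could be recovered, the branch for levels was used, and the branch for centred ratios was run as an alternative.

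Probe sets were named through the platform annotation supplied with the table. Of 22283 probe sets, 19071 had 1 gene symbol, 1043 several and 2169 none, and the last 2 kinds were not tested. Of the 19071, 19059 were matched to a current symbol by Entrez identifier. Each of 11963 genes was represented by its probe set with the highest mean, and 3589 genes below the 30th percentile of mean level, a rescaled signal of 71.7, were left out. The 8374 genes left were tested, of which 3598 had several probe sets. No genome coordinates were used here. The 68 control probe sets served only to describe the arrays.

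Each comparison was tested with limma (version 3.58.1, R version 4.3.3), lmFit and eBayes, as a contrast in 1 model with a mean for each of the 9 groups over all 26 arrays. The spread was shared over all groups with 17 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Lines with 1 array in their group were thus assumed to vary like the groups with replicates. An adjusted p below is limma's unless camera or an exact test is named. Changes are given as log2 change ± its standard error.

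Genes were named by a rule. Among genes past the threshold with an absolute log2 change of at least 1 and no overlap between the values of the groups, it took the 8 with the largest rise and the 8 with the largest fall. It added up to 4 members of each gene list past its test, with the largest moderated t. Members of the known bone list in bone against weak lines, of the known lung list in lung against weak lines, and of both in the comparisons of hetero-fused lines could be named as well. Where no gene passed, it took the 3 with the smallest p on each side. Of the genes that the rule gave, the text names those that serve a comparison or list. Genes of near-identical families (histones, MAGE genes, HLA) were named as members whose probe sets can cross-hybridise.

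Gene lists (30) were fixed for metastasis to bone and lung, signalling, matrix, proliferation, metabolism and the markers of other cell types. Camera, from limma, tested the 29 lists with at least 3 tested members in each comparison, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. The known bone and known lung lists come from earlier work on sublines of this cell line, perhaps on some of these arrays. Lists can share members, so their calls are not separate results. MMP1 is in both known lists, and IL11 in the known bone and bone resorption lists. The NF-kappaB cytokine list shares IL6, CXCL8 and IL1B with bone resorption, and CXCL1 and PTGS2 with the known lung list. SPARC and TNC are in the known lung and extracellular matrix lists. Of 41 list calls over 8 comparisons, 2 held with an estimated correlation. Endothelial markers had too few tested members, and 13 lists were not past the test in any comparison. Their smallest camera adjusted p was 0.055 for matrix proteases, 0.064 for adhesion receptors, 0.092 for fibroblast markers, 0.094 for TGF-beta targets, 0.096 for p53 targets and 0.099 for osteoblast and osteoclast markers. It was 0.11 for cell fusion genes, 0.14 for epithelial genes, 0.14 for leukocyte markers, 0.19 for mesenchymal genes, 0.20 for endoplasmic reticulum stress, 0.23 for lung epithelium markers and 0.29 for luminal breast markers.

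Signature positions used a limma fit of the bone-, lung- and weakly metastatic lines alone. Genes past the threshold with an absolute log2 change of at least 1 formed a bone signature of 45 genes (29 higher, 16 lower) and a lung signature of 431 genes (172 higher, 259 lower). A line's position is its signed distance from the weak mean over these genes, divided by that of the bone or lung mean, so that 0 is the weak mean and 1 the metastatic mean. Each of these training lines was scored with a signature derived without it. A position between the partners was computed over 652 genes that differed by a log2 value of at least 1 between Bm and Lm, with LLm as 0 and BBm as 1. Positions were compared by 2-sided exact permutation tests over all splits of the lines, and by an exact sign-flip test.

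The recovery of signals was tested on 1500 simulated probe sets, of which 1500 were recovered. The limma step was tested on 8374 simulated genes with log2 changes of 0.5, 1 and 2. For bone against weak lines it recovered 23.9%, 79.1% and 100% of the changed genes, for hetero-fused lines against the lung partner side 2.99%, 37.3% and 87.9%, and for self-fused against unfused partner lines 4.48%, 26.9% and 89.4%. The simulated lines were independent, had no array sets and shared the same spread of a gene in all groups. These shares therefore do not test the assumption of equal spread. Camera called the moved list in 8 of 8 simulated comparisons and an unmoved list in 0 of 8. The simulated genes varied independently, so this does not test the preset correlation between genes of a list. A simulated signature position of 0.7 was returned as 0.703 and a simulated position between partners of 0.3 as 0.306. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.

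The groups, tests, gene lists, naming rule and the following alternatives were fixed before the data were examined: quantile normalization, no filter, the mean of a gene's probe sets, pseudocounts of 1 and 64, array weights, a fit of only the groups compared, each line left out in turn, BLm-DRUG averaged with its clones, each partner joined with its self-fused line, other choices of signature and partner genes, and line types by signature label with the fusion arrays as a covariate. Added after the data were seen were the signals at the trimmed mean, the centred ratios, 3 array sets as covariates, the array median or the actin ratio as a covariate, hetero-fused lines with or without a clone number alone, the positions with BLm-DRUG averaged with its clones, and bone lines 1833 and SCP46 left out. The closest pair of arrays, BLm-FACS and BLm-DRUG, correlated at r = 0.984 over genes and shared 0 identical values, so no array was a copy of another.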

Results

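Gene expression was measured in 26 lines derived from MDA-MB-231, a human breast cancer cell line, with 1 array for each line. Besides the parental line there were 5 lines that the labels call bone-metastatic (1833, SCP46, SCP25, SCP20 and SCP14), 5 called lung-metastatic (3481, 4142, 4173, 4180 and 4175) and 6 called weakly metastatic (SCP43, SCP32, SCP28, SCP6, SCP4 and SCP3). The other 9 lines came from cell fusion experiments. Bm is a bone-tropic and Lm a lung-tropic partner line, BBm and LLm are fusions of a partner with itself, and 5 hetero-fused lines came from fusing Bm with Lm. Of these, BLm-FACS and BLm-DRUG carried no clone number, and BLm-DRUG-8, BLm-DRUG-12 and BLm-DRUG-18 carried one. The titles name the 3 as clones of BLm-DRUG, yet the main tests counted the 5 as independent lines, which the labels do not support. The p-values for hetero-fused lines assume that independence, and BLm-DRUG was averaged with its clones as an alternative. The number of arrays limits the precision. Replicates are different lines, not repeated cultures, so each p-value measures a difference against the spread between single-array lines, which can itself be technical. Bm, Lm, BBm, LLm and the parental line had no replicates. No paired analysis was possible because replicate numbers only follow the order of deposition.

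The control probe sets divided the arrays into 3 sets. The bacterial hybridisation controls, which are added to each sample in a fixed amount, had a mean log2 signal of 11.61 ± 0.30 (SD, n = 5) on the arrays of the bone lines, 11.79 ± 0.11 (SD, n = 6) on those of the weak lines and 11.32 on that of the parental line. They were at 10.27 ± 0.26 (SD, n = 5) on the arrays of the lung lines. On the arrays of the fusion experiments they were at 9.64 ± 0.09 (SD, n = 5) for the hetero-fused lines, 9.67 for Bm, 9.66 for Lm, 9.52 for BBm and 9.62 for LLm. The 18S ribosomal RNA probe sets had a mean log2 signal of 12.10 ± 0.87 (SD, n = 5) on the arrays of the lung lines, against 4.38 to 6.76 on all other arrays. By these controls, the comparison of bone with weak lines and those among the fusion lines lay within 1 array set. The sets were drawn from the control signals, as the labels name no batch. Among the bone, weak and parental lines the hybridisation controls ran from 11.15 in 1833 to 11.93 in SCP46. A batch within that set is therefore not excluded. Lung against weak, bone against lung and hetero-fused against weak lines each lay across sets, so the line type and the array set cannot be told apart there. The actin 3'/5' log2 ratio, 1 of 2 measures of RNA integrity, followed the groups. It was 0.74 ± 0.30 (SD, n = 6) in the weak lines, from 0.34 to 1.09, against 0.09 ± 0.08 (SD, n = 5) in the lung lines and -0.01 ± 0.06 (SD, n = 5) in the hetero-fused lines, without overlap. The bone lines ran from -0.41 to 2.31, the latter SCP46. The GAPDH 3'/5' log2 ratio, the other measure, overlapped, from -0.07 to 0.06 in the weak, -0.19 to 0.08 in the lung and -0.29 to -0.03 in the hetero-fused lines. Whether RNA integrity differed between these groups therefore stays open. In the bone lines the GAPDH ratio ran from -0.07 to 0.33, the latter again SCP46. SCP46 had the highest value of all lines on both measures, and the lowest array median signal, at 115. With the actin ratio as a covariate limma called 2141 genes in lung against weak lines, 686 higher. In hetero-fused against weak lines it called 2679, 805 higher. Without the covariate the counts were 2593 and 3335. The covariate does not remove the overlap with the array sets.

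**Figure D1:**
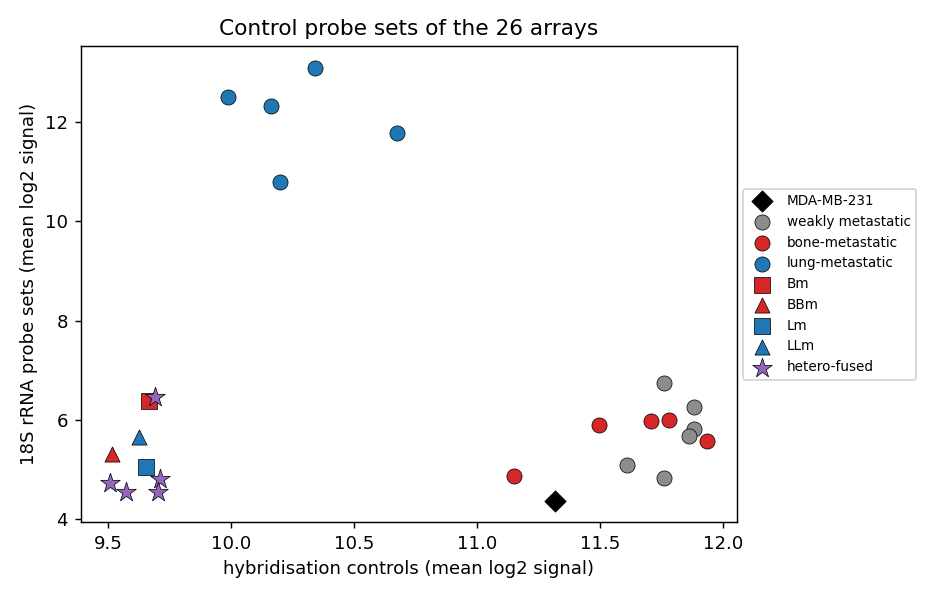
Control probe sets of the 26 arrays, with the log2 signal of the hybridisation controls and of 18S ribosomal RNA for each line. The lung lines, with hybridisation controls from 9.99 to 10.67, lay between the fusion arrays and the arrays of the bone, weak and parental lines, and had 18S signals from 10.8 to 13.1.

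Bone-metastatic lines were compared with weakly metastatic lines to find the genes that mark lines strongly metastatic to bone. CXCR4, the gene of a chemokine receptor, had a level of 10.36 ± 0.46 (SD, n = 5) in the bone lines and 7.74 ± 0.43 (SD, n = 6) in the weak lines, with 8.48 in the parental line as background. It rose by 2.62 ± 0.20 (limma adjusted p = 7.87e-08). INHBA, the gene of an activin subunit, rose by 2.92 ± 0.34 (adjusted p = 3.8e-05), from 4.75 ± 0.16 (SD, n = 6) to 7.67 ± 0.999 (SD, n = 5), with 6.52 in the parental line. PPL, the gene of periplakin, fell by 3.14 ± 0.36 (adjusted p = 3.8e-05). DLC1 fell by 3.19 ± 0.39 (adjusted p = 6.71e-05), but of its 2 other probe sets 1 had the same sign. Of 8374 genes, 160 passed, 78 higher and 82 lower, of which 61 changed at least 2-fold, and 1421 had an unadjusted p under 0.05. With each array at the same trimmed mean, 119 were higher and 83 lower.

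Other genes that rose in the bone lines were NAP1L3 by 3.37 ± 0.52, ADAMTS1 by 2.74 ± 0.45, DAPK1 by 2.38 ± 0.24, SRGN by 2.34 ± 0.36, PTK7 by 2.16 ± 0.29 and SOCS2 by 1.88 ± 0.25. S100A2 fell by 2.11 ± 0.45, CYP1B1 by 1.59 ± 0.25 (adjusted p = 0.56 with the centred ratios), CTSB by 1.40 ± 0.25 and ARHGEF10 by 1.28 ± 0.20, and CST6 fell as well (adjusted p = 0.0051). The call of S100A2 ended without 1833 (adjusted p = 0.056). MALL, at -1.31 ± 0.28 (adjusted p = 0.017), lost its call without SCP14 (adjusted p = 0.058). The count of genes was 402 without SCP46, the line with the highest actin ratio. It was 70 without SCP14, 75 without SCP3, 87 without 1833, 89 without SCP25 and 94 without SCP43. A fit of the bone and weak lines alone, with the spread of these lines only, called 18 genes, all among the 160.

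The known bone metastasis genes were higher as a list (camera adjusted p = 5.56e-14, and adjusted p = 0.0028 with an estimated correlation), with a median log2 change of 2.22. Of 8 tested, 4 rose, 0 fell and 4 were not past the threshold, and 8 rose adjusted over the list alone. This list and the known lung list come from sublines of this cell line and are not independent evidence. CXCR4, ADAMTS1 and SRGN were among those that rose. MMP1 rose by 4.25 ± 1.09 (adjusted p = 0.045), a call that quantile normalization ended (adjusted p = 0.052) and that ended without 1833, SCP14, SCP20, SCP25, SCP3, SCP4 or SCP6 (adjusted p from 0.052 to 0.11). IL11, at 2.10 ± 0.60 (adjusted p = 0.073), FST, at 1.35 ± 0.39 (adjusted p = 0.076), CCN2, at 0.91 ± 0.27 (adjusted p = 0.087), and FGF5, at 1.17 ± 0.42 (adjusted p = 0.16), did not pass. IL11 passed without SCP20 (adjusted p = 0.049) or SCP28 (adjusted p = 0.012), CCN2 without SCP28 (adjusted p = 0.0025), and FST without SCP14, SCP46 or SCP28 (adjusted p from 0.039 to 0.048). With the fusion arrays as a covariate IL11 (adjusted p = 0.046), CCN2 (adjusted p = 0.028) and FGF5 (adjusted p = 0.046) passed, and IL11 also with 3 array sets (adjusted p = 0.032), with the mean of its probe sets (adjusted p = 0.035) and with the larger pseudocount (adjusted p = 0.045). The MMP1 values overlapped, with 1833, SCP20 and SCP46 below the highest weak line at 13.37. MMP1 also failed with array weights (adjusted p = 0.066) and without the filter (adjusted p = 0.069).

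Other lists passed in the same comparison only with the preset correlation. Immediate early genes were higher (camera adjusted p = 2.2e-06, and adjusted p = 0.27 with an estimated correlation). Of 19, 2 rose, 0 fell and 17 were not past the threshold, and 7 rose adjusted over the list alone. DUSP1 rose by 1.74 ± 0.28 and JUND by 0.66 ± 0.17 (adjusted p = 0.042), the latter not in 8 of the fits that left out 1 line (adjusted p from 0.051 to 0.11, without 1833, SCP14, SCP46, SCP3, SCP6, SCP28, SCP32 or SCP43). NF-kappaB cytokines were higher (camera adjusted p = 0.00077, and adjusted p = 0.51 with an estimated correlation). Of 13, 0 rose and 0 fell, also adjusted over the list alone, and CXCL8, at 2.76 ± 0.89 (adjusted p = 0.11), passed only without SCP20 (adjusted p = 0.021). Regulators of bone resorption were higher (camera adjusted p = 0.032, and adjusted p = 0.51 with an estimated correlation), with 0 of 7 past the threshold and 2 higher adjusted over the list alone. Known lung metastasis genes were higher (camera adjusted p = 0.032, and adjusted p = 0.51 with an estimated correlation). Of 17, 1 rose and 0 fell, and 3 rose and 1 fell adjusted over the list alone. The 1 that rose was MMP1, which the known bone list holds as well. Genes of HLA class II presentation, whose probe sets can cross-hybridise, were higher (camera adjusted p = 0.031, and adjusted p = 0.54 with an estimated correlation), with 0 of 10 past the threshold, also adjusted over the list alone. Ribosomal protein genes were lower (camera adjusted p = 0.0075, and adjusted p = 0.54 with an estimated correlation), with 0 of 21 past the threshold, also adjusted over the list alone, and a median of -0.16 that was -0.02 under quantile normalization.

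Of these 6 list calls, those of the immediate early genes and NF-kappaB cytokines were kept under both other scalings and with any 1 line left out. The other 4 ended under quantile normalization: bone resorption (camera adjusted p = 0.061), known lung genes (adjusted p = 0.087), HLA class II (adjusted p = 0.071) and ribosomal protein genes (adjusted p = 0.53). Without SCP46 the same 4 ended as well (adjusted p from 0.072 to 0.092), and without SCP6 bone resorption and known lung genes did (adjusted p = 0.18 for both). Over all comparisons, 17 of 41 list calls were kept in both kinds of alternative, 27 with any 1 line left out and 23 under both other scalings.

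**Figure D2:**
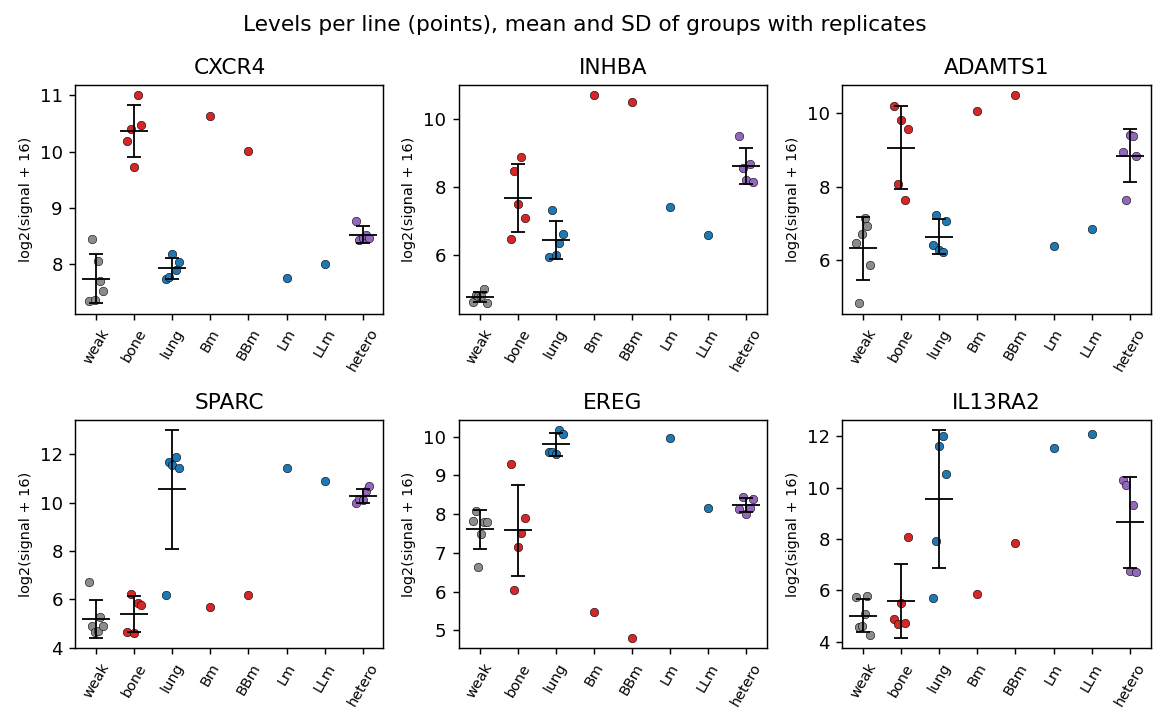
Log2 levels of CXCR4, INHBA, ADAMTS1, SPARC, EREG and IL13RA2 in each line, 1 point per line, with mean and SD for the groups with replicates. CXCR4 lay at 10.36 ± 0.46 in the bone lines and 8.53 ± 0.14 in the hetero-fused lines, and SPARC at 10.28 ± 0.30 in the hetero-fused lines and 5.19 ± 0.78 in the weak lines.

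Lung-metastatic lines were compared with weakly metastatic lines to find the genes that mark lines strongly metastatic to lung. SPARC, the gene of a matrix glycoprotein, had a level of 10.55 ± 2.45 (SD, n = 5) in the lung lines and 5.19 ± 0.78 (SD, n = 6) in the weak lines, with 4.38 in the parental line as background. It rose by 5.36 ± 0.71 (limma adjusted p = 2.19e-05). IL13RA2, the gene of a decoy receptor for interleukin 13, rose by 4.54 ± 0.93 (adjusted p = 0.0011), and EREG, the gene of a growth factor of the EGF family, by 2.20 ± 0.36 (adjusted p = 0.00016). Lung line 3481 lacked the rise of the first 2 genes, with SPARC at 6.18 against 6.72 in SCP3, and IL13RA2 at 5.70 against 5.79 in SCP32. The other lung lines lay from 11.46 to 11.91 for SPARC and 7.92 to 12.00 for IL13RA2. PNPLA4 fell by 3.79 ± 0.23 (adjusted p = 4.71e-10), from 9.05 ± 0.60 (SD, n = 6) to 5.26 ± 0.11 (SD, n = 5), with 8.94 in the parental line. Of 8374 genes, 2593 passed, 688 higher and 1905 lower, and 435 changed at least 2-fold. The split turned with the scaling, to 985 higher and 1191 lower under quantile normalization and 1435 higher and 997 lower at the trimmed mean. The median over all genes was -0.13, and 0.08 at the trimmed mean.

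Other genes higher in the lung lines were CSF3 by 3.49 ± 0.58, COL6A2 by 3.26 ± 0.60, FSCN1 by 2.46 ± 0.37 and TNFSF4 by 2.33 ± 0.28. COL6A1 was higher by 2.38 ± 0.39, with the same sign in 4 of its 7 other probe sets. C4BPB, NNMT, FCGRT, EFEMP1, C2orf68 and DOCK2 were lower by log2 changes of -2.46 to -2.08. H3-3A, a histone gene whose probe sets can cross-hybridise, was lower by 2.33. MAGEB2, of a family whose probe sets can cross-hybridise, was higher by 2.28. With the 3 array sets as covariates, the lung lines, a set of their own, do not enter the difference. It then rests on Lm and LLm against Bm and BBm, added to bone against weak and parental lines. In that fit 3 genes passed. Among them were CSF3, at 5.99 (adjusted p = 0.042), and EREG, at 3.86 (adjusted p = 0.042), while SPARC (adjusted p = 0.21), IL13RA2 (adjusted p = 0.43) and PNPLA4 (adjusted p = 0.53) lost their calls and C2orf68 turned to 0.54, DOCK2 to 0.69 and TNC to -0.31. With the median signal of each array as a covariate, 605 genes passed.

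The known lung metastasis genes were higher as a list (camera adjusted p = 4.66e-09, and adjusted p = 0.029 with an estimated correlation), with a median of 1.54. Of 17 tested, 11 rose, 0 fell and 6 were not past the threshold, and 12 rose adjusted over the list alone. Besides SPARC, IL13RA2, EREG and FSCN1 these were CXCL1, PTGS2, KYNU, MMP2, VCAM1, TNC and LTBP1, with changes of 1.06 to 3.25. The lung and weak values overlapped for VCAM1, KYNU, MMP2 and TNC as well. The call of TNC ended without 4175 (adjusted p = 0.068), and without 4180 those of VCAM1 (adjusted p = 0.054) and LTBP1 (adjusted p = 0.069). Extracellular matrix genes were higher (camera adjusted p = 0.0058, and adjusted p = 0.17 with an estimated correlation), with 7 of 24 higher and 1 lower, the same counts adjusted over the list alone. NF-kappaB cytokines were higher (camera adjusted p = 0.00059, and adjusted p = 0.51 with an estimated correlation), with 6 of 13 higher and 0 lower, also adjusted over the list alone, among them IL6 by 1.46. Immediate early genes were higher (camera adjusted p = 0.021, and adjusted p = 0.51 with an estimated correlation), with 5 of 19 higher and 0 lower, also adjusted over the list alone, among them EGR1 by 1.07, a list call that ended without SCP4 (adjusted p = 0.080).

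Lists of housekeeping functions were lower in the lung lines, by amounts that depended on the scaling. Ribosomal protein genes were lower (camera adjusted p = 5.02e-11, and adjusted p = 0.17 with an estimated correlation). All 21 fell, also adjusted over the list alone, with a median of -0.67 that was -0.44 at the trimmed mean and -0.09 under quantile normalization, where 2 fell. RPL14 fell by 0.94, while RPL32, at -0.82, turned to 0.18 with the 3 array sets as covariates, and RPL32 and RPS6 lost their calls under quantile normalization. Genes of oxidative phosphorylation were lower (camera adjusted p = 0.00016, and adjusted p = 0.45 with an estimated correlation). Of 24, 16 fell, 0 rose and 8 were not past the threshold, 17 fell adjusted over the list alone, and 5 fell under quantile normalization. ATP5F1C fell by 0.93, and NDUFS1, at -0.94, turned to 0.011 with the 3 array sets. Mitosis genes were lower (camera adjusted p = 0.027, and adjusted p = 0.52 with an estimated correlation). Of 25, 11 fell, 0 rose and 14 were not past the threshold, and 16 fell adjusted over the list alone, while 3 fell and 1 rose under quantile normalization. CCNB1 fell by 0.77, and AURKA by 0.80 with the same sign in 1 of its 2 other probe sets. The list calls ended under quantile normalization for ribosomal protein genes (adjusted p = 0.37), oxidative phosphorylation (adjusted p = 0.17) and mitosis (adjusted p = 0.37). That of mitosis also ended at the trimmed mean and without 4142 (adjusted p = 0.061 for both), and without SCP4 (adjusted p = 0.064). With the 3 array sets as covariates the ribosomal protein list turned to higher and oxidative phosphorylation lost its call (adjusted p = 0.68 for both). The lung lines do not enter that difference, so their own direction was not separated from the array sets.

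Bone-metastatic and lung-metastatic lines were compared directly, to find the genes by which the organ-specific lines differ. PNPLA4 was higher in the bone lines by 3.50 ± 0.24 (limma adjusted p = 5.6e-09), at 8.76 ± 0.25 (SD, n = 5) against 5.26 ± 0.11 (SD, n = 5), with 8.94 in the parental line. CXCR4 was higher by 2.43 ± 0.21 (adjusted p = 3.96e-07), against a background of 7.93 ± 0.19 (SD, n = 5) in the lung lines. SPARC was lower by 5.14 ± 0.74 (adjusted p = 5.78e-05), although bone line SCP14 at 6.21 lay above lung line 3481, and EREG by 2.22 ± 0.38 (adjusted p = 0.00024). Of 8374 genes, 2341 passed, 1583 higher and 758 lower in the bone lines, and 485 changed at least 2-fold. The split was 1122 higher and 1049 lower under quantile normalization, and 957 higher and 1402 lower at the trimmed mean.

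EFEMP1, FCGRT, C4BPB, MATN2, NNMT and C2orf68 were higher in the bone lines by 2.58 to 2.99. COL6A2, COL6A1, PPL, GPRC5C, SERPINA1, CSF3, DLC1 and COL7A1 were lower, from -3.56 to -2.56. With the 3 array sets as covariates, the difference rests on Bm and BBm against Lm and LLm, and 90 genes passed. Among them were EFEMP1 at 4.06 (adjusted p = 0.00036), CXCR4 at 2.44 (adjusted p = 0.00056) and SPARC at -5.25 (adjusted p = 0.015), while PNPLA4 lost its call (adjusted p = 0.17), C2orf68 turned to -0.21 and RPL14 to -0.070. With the median signal of each array as a covariate, 1257 genes passed.

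The known bone metastasis genes were higher in the bone lines (camera adjusted p = 0.0020, and adjusted p = 0.30 with an estimated correlation). Of 8, 5 were higher, 0 lower and 3 not past the threshold, and 7 were higher adjusted over the list alone, among them IL11 by 2.45, ADAMTS1 by 2.42 and FST by 1.78. The values overlapped for IL11, with SCP20 below the highest lung line, and for FST, with SCP14 below it. The known lung metastasis genes were lower (camera adjusted p = 9.59e-05, and adjusted p = 0.30 with an estimated correlation). Of 17, 9 were lower, 0 higher and 8 not past the threshold, and 10 were lower adjusted over the list alone, among them VCAM1 by 1.97 and MMP2 by 1.53. Extracellular matrix genes were lower (camera adjusted p = 0.012, and adjusted p = 0.30 with an estimated correlation), with 7 of 24 lower and 1, COL8A1 at 1.72, higher, also adjusted over the list alone. Genes of HLA class I presentation, of which the HLA members can cross-hybridise, were higher (camera adjusted p = 0.012, and adjusted p = 0.70 with an estimated correlation). Of 10, 7 were higher and 1 lower, 8 higher and 1 lower adjusted over the list alone, and 4 higher under quantile normalization. TAP2 was higher by 0.97 and PSMB9, with 1833 below the highest lung line, by 0.98. Ribosomal protein genes were higher (camera adjusted p = 4.14e-07, and adjusted p = 0.34 with an estimated correlation), 19 of 21 past the threshold, also adjusted over the list alone, with a median of 0.49 that was 0.06 under quantile normalization, where 1 was higher. Genes of oxidative phosphorylation were higher (camera adjusted p = 0.012, and adjusted p = 0.83 with an estimated correlation), 11 of 24 higher and 1 lower, 12 and 1 adjusted over the list alone, and 4 higher and 2 lower under quantile normalization. The list calls ended there for extracellular matrix (adjusted p = 0.084), HLA class I (adjusted p = 0.11), ribosomal protein genes (adjusted p = 0.88) and oxidative phosphorylation (adjusted p = 0.54). With the 3 array sets as covariates the ribosomal protein list (adjusted p = 0.14) and oxidative phosphorylation (adjusted p = 0.75) turned to lower, and without 4142 the latter call ended as well (adjusted p = 0.054).

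Hetero-fused lines were compared with weakly metastatic lines to see which genes mark hybrids against weakly metastatic relatives. SPARC rose by 5.09 ± 0.71 (limma adjusted p = 1.48e-05), to 10.28 ± 0.30 (SD, n = 5) from 5.19 ± 0.78 (SD, n = 6), with 4.38 in the parental line. CXCR4 rose by 0.79 ± 0.20 (adjusted p = 0.0041), to 8.53 ± 0.14 (SD, n = 5) against at most 8.45 in a weak line, with 8.48 in the parental line. Its values overlapped, with BLm-DRUG at 8.42 below the highest weak line. INHBA rose by 3.87 ± 0.34 (adjusted p = 1.09e-07), although its 1 other probe set had the opposite sign. PNPLA4 fell by 3.42 ± 0.23 (adjusted p = 3.73e-09). Of 8374 genes, 3335 passed, 901 higher and 2434 lower, and 732 changed at least 2-fold. The split was 1253 higher and 1504 lower under quantile normalization, and 1953 higher and 1259 lower at the trimmed mean. The median over all genes was -0.17, and 0.11 at the trimmed mean.

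LCP1, IL13RA2, CPA3, NAP1L3 and APP rose by 2.85 to 3.79. IL13RA2 lay at 10.31 in BLm-FACS and 10.11 in BLm-DRUG but from 6.70 to 9.33 in the clones, which alone rose by 2.58 and did not pass (adjusted p = 0.064). ID3, CST6, MALL, P2RY2, CYP1B1 and KRT19 fell, with changes of -3.13 to -2.54, and so did H3-3A, a histone gene whose probe sets can cross-hybridise, by 2.48. With line types by signature label and the fusion arrays as a covariate, 41 genes passed. They included SPARC at 4.65 (adjusted p = 0.023), NAP1L3 at 3.16 (adjusted p = 0.038), PNPLA4 at -2.67 (adjusted p = 0.017), CYP1B1 at -2.44 (adjusted p = 0.00068), INSIG1 at 1.61 (adjusted p = 0.049) and DUSP1 at 1.59 (adjusted p = 0.049), but not CXCR4 (adjusted p = 0.23) or INHBA (adjusted p = 0.13). With 3 array sets limma called 0 genes. With BLm-DRUG and its clones averaged 1574 passed, with BLm-FACS and BLm-DRUG alone 1662, and with the median signal of each array as a covariate 706.

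Both known metastasis lists were higher in the hetero-fused than in the weak lines. Of 8 known bone genes, 5 rose, 0 fell and 3 were not past the threshold, and 6 rose adjusted over the list alone (camera adjusted p = 0.00028, and adjusted p = 0.25 with an estimated correlation). These included IL11 by 2.52, ADAMTS1 by 2.51, SRGN by 2.19 and FST by 1.47. Of 17 known lung genes, 6 rose, 2 fell and 9 were not past the threshold, and 8 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00086, and adjusted p = 0.28 with an estimated correlation). KYNU rose by 1.77 and PTGS2 by 1.53, and ID1 fell by 2.42. The hetero-fused and weak values overlapped for IL11, KYNU, PTGS2 and FSCN1 as well as for CXCR4. PTGS2 rose by 2.54 in BLm-FACS and BLm-DRUG but by 0.86 in the clones (adjusted p = 0.16). FSCN1, at 0.96 (adjusted p = 0.040), turned to -0.37 with the array median as a covariate and lost its call without BLm-FACS, BLm-DRUG, BLm-DRUG-12, BLm-DRUG-18, SCP3, SCP6 or SCP43 (adjusted p from 0.052 to 0.11).

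Further lists were higher in the hetero-fused than in the weak lines with the preset correlation. NF-kappaB cytokines had 7 of 13 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.00028, and adjusted p = 0.41 with an estimated correlation). CXCL1 rose by 3.35, CSF3 by 2.72 and IL6 by 2.13, while IL1B, at 2.49, turned to -0.084 with the fusion arrays and to -0.47 with 3 array sets as covariates. BLm-FACS and BLm-DRUG carried most of this rise. In the clones alone CXCL1 rose by 2.05 (adjusted p = 0.087) against 5.30 in these 2 lines, IL1B by 1.26 (adjusted p = 0.089) against 4.34, CSF3 by 1.53 (adjusted p = 0.023) against 4.49 and IL6 by 1.70 (adjusted p = 0.0025) against 2.78. The list passed in the clones alone too (camera adjusted p = 0.017). Cholesterol synthesis genes had 5 of 15 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.41 with an estimated correlation). INSIG1 rose by 1.17 and MVK by 1.14, and PMVK fell by 0.86. Cancer-testis genes, whose probe sets can cross-hybridise, had 3 of 5 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.0072, and adjusted p = 0.32 with an estimated correlation). The family members MAGEA12 and MAGEC1 rose by 1.45 and 1.37. Immediate early genes had 5 of 19 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.023, and adjusted p = 0.41 with an estimated correlation). DUSP1 rose by 2.13 and KLF6 by 1.41. The call of the cytokine list ended with the fusion arrays as a covariate (adjusted p = 0.26), that of the cancer-testis list under quantile normalization (adjusted p = 0.056), that of the known lung list with the array median (adjusted p = 0.15) and that of the immediate early list without SCP4 (adjusted p = 0.11). The immediate early call also ended without BLm-FACS (camera adjusted p = 0.052) and with the clones alone (camera adjusted p = 0.12).

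Ribosomal protein, oxidative phosphorylation and DNA replication genes were lower in the hetero-fused than in the weak lines. All 21 ribosomal protein genes fell, also adjusted over the list alone (camera adjusted p = 6.07e-13, and adjusted p = 0.25 with an estimated correlation). Their median was -0.93, with RPL14 at -1.05, and was -0.63 at the trimmed mean and -0.12 under quantile normalization, where 2 fell and RPS6 lost its call. Of 24 genes of oxidative phosphorylation, 18 fell and 0 rose, 20 and 1 adjusted over the list alone (camera adjusted p = 0.00028, and adjusted p = 0.41 with an estimated correlation). NDUFB3 fell by 1.07, and under quantile normalization 6 of the list fell and 1 rose. Of 24 DNA replication genes, 12 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.44 with an estimated correlation). POLA1 fell by 1.47, and under quantile normalization 6 of the list fell and 1 rose. There the calls ended for all 3 lists, at adjusted p = 0.34, 0.49 and 0.28. The DNA replication list turned to higher with 3 array sets (adjusted p = 0.28), and its call ended with the fusion arrays as a covariate (adjusted p = 0.64), with the clones alone (adjusted p = 0.13) and with the actin ratio (adjusted p = 0.11).

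Hetero-fused lines were compared with the mean of Bm and BBm, to see what hybrids differ in from their bone-tropic partner. EREG rose by 3.09 ± 0.50 (limma adjusted p = 0.0041), to 8.23 ± 0.18 (SD, n = 5) from 5.48 in Bm and 4.80 in BBm, with 9.97 in Lm. SPARC rose by 4.36 ± 0.98 (adjusted p = 0.042), to 10.28 from 5.67 and 6.17, with 11.43 in Lm. CXCR4 fell by 1.79 ± 0.28 (adjusted p = 0.0040), from 10.63 in Bm and 10.01 in BBm, with 7.75 in Lm. TNFSF15 fell by 2.37 ± 0.34 (adjusted p = 0.0024), and MMP3 fell to 7.43 ± 0.18 (SD, n = 5) from a mean of 9.43 in Bm and BBm (limma adjusted p = 0.0013). INSIG1, a regulator of cholesterol synthesis, rose by 2.38 ± 0.41 (adjusted p = 0.0054). Of 8374 genes, 45 passed, 29 higher and 16 lower, and 904 had an unadjusted p under 0.05. Under quantile normalization 56 were higher and 49 lower, and at the trimmed mean 35 were higher and 32 lower.

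CPE, CSGALNACT1, PLXNA1, GSR and DYNC2I1 rose by 1.88 to 2.35, and FERMT1, DAPK1 and TEAD1 fell, with changes of -1.81 to -1.56. NRG1 fell by 1.75, with the same sign in 4 of its 5 other probe sets, and the histone gene H2BC5, whose probe sets can cross-hybridise, by 1.65. The count was 11 without Bm, all higher, and 14 without BBm, 3 higher and 11 lower, so the split turned with the partner line left out. It was 27 without BLm-DRUG, 59 with BLm-FACS and BLm-DRUG alone, 51 higher and 8 lower, and 46 with the clones alone, 18 higher and 28 lower. All 17 named calls ended without Bm, BBm or both, as for CXCR4 without Bm (adjusted p = 0.16), SPARC without Bm (adjusted p = 0.40) and EREG without BBm (adjusted p = 0.11). With BLm-DRUG and its clones averaged, 3 genes passed.

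Cholesterol synthesis genes were higher in the hetero-fused lines than on the bone partner side (camera adjusted p = 5.75e-07, and adjusted p = 0.70 with an estimated correlation), with a median of 0.67. Of 15, 1 rose, 0 fell and 14 were not past the threshold, and 6 rose adjusted over the list alone. DHCR7, at 1.17 (adjusted p = 0.089), and HMGCS1, at 1.05 (adjusted p = 0.21), did not pass. Hypoxia and glycolysis genes were higher (camera adjusted p = 0.00043, and adjusted p = 0.70 with an estimated correlation), with 0 of 20 past the threshold, and 6 higher and 1 lower adjusted over the list alone. DDIT4, at 1.55 (adjusted p = 0.083), passed without BLm-DRUG-12 (adjusted p = 0.038) and under quantile normalization (adjusted p = 0.032). DNA replication genes were higher (camera adjusted p = 0.013, and adjusted p = 0.95 with an estimated correlation), with 1 of 24, MCM5 by 0.95, past the threshold and 2 higher adjusted over the list alone. The known bone metastasis genes were lower (camera adjusted p = 0.019, and adjusted p = 0.70 with an estimated correlation), with 1 of 8, CXCR4, past the threshold, also adjusted over the list alone. The call of DNA replication ended without Bm (adjusted p = 0.066) and with BLm-DRUG and its clones averaged (adjusted p = 0.11), and that of the known bone list at the trimmed mean (adjusted p = 0.052).

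Hetero-fused lines were compared with the mean of Lm and LLm, to see what hybrids differ in from their lung-tropic partner. EFEMP1, the gene of a matrix protein, rose by 2.76 ± 0.45 (limma adjusted p = 0.015), to 10.63 ± 0.24 (SD, n = 5) from 8.37 in Lm and 7.38 in LLm, with 12.11 in Bm and 12.02 in the parental line. SOCS2 rose by 1.82 ± 0.34 (adjusted p = 0.043). CYP1B1 fell by 1.90 ± 0.34 (adjusted p = 0.040) and ALDH3A2 by 1.61 ± 0.26 (adjusted p = 0.015). These 4 of 8374 genes passed, and 887 had an unadjusted p under 0.05. The count was 89 under quantile normalization, with 55 higher, and 31 at the trimmed mean, with 19 higher. It was 0 without LLm, 7 without Lm, 2 without BLm-DRUG-8 or BLm-DRUG-18, and 0 with BLm-DRUG and its clones averaged. EFEMP1 lost its call without LLm (adjusted p = 0.24), ALDH3A2 without Lm (adjusted p = 0.056) or LLm (adjusted p = 0.14), SOCS2 without LLm (adjusted p = 0.40) or any 1 of the 4 drug-selected lines (adjusted p from 0.053 to 0.10), and CYP1B1 without any 1 of the 7 lines compared (adjusted p from 0.053 to 0.15).

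Cholesterol synthesis genes were higher in the hetero-fused lines than on the lung partner side too (camera adjusted p = 1.55e-06, and adjusted p = 0.53 with an estimated correlation), with a median of 0.56. Of 15, 0 passed, and 5 rose adjusted over the list alone. INSIG1, at 1.66 (adjusted p = 0.078), DHCR7, at 1.16 (adjusted p = 0.10), and MSMO1, at 1.22 (adjusted p = 0.11), did not pass, although INSIG1 did under quantile normalization (adjusted p = 0.037) and with array weights (adjusted p = 0.022). The known bone metastasis genes were higher (camera adjusted p = 0.010, and adjusted p = 0.53 with an estimated correlation), with 0 of 8 past the threshold and 3 higher adjusted over the list alone. ADAMTS1, at 2.21 (adjusted p = 0.14), and FST, at 1.67 (adjusted p = 0.22), did not pass. The known lung metastasis genes were lower (camera adjusted p = 0.024, and adjusted p = 0.53 with an estimated correlation), with 0 of 17 past the threshold, also adjusted over the list alone, and IL13RA2 at -3.19 (adjusted p = 0.35). With BLm-FACS and BLm-DRUG alone this list did not pass (camera adjusted p = 0.35), so its fall lay mainly in the clones. This list call ended under quantile normalization (adjusted p = 0.075), at the trimmed mean (adjusted p = 0.099) and with BLm-DRUG and its clones averaged (adjusted p = 0.076), and that of the known bone list without LLm (adjusted p = 0.076).

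The bone partner side, the mean of Bm and BBm, was compared with the lung partner side, the mean of Lm and LLm. TNFSF15, a cytokine gene, was higher by 3.95 ± 0.41 (limma adjusted p = 1.88e-05), at 9.94 in Bm and 9.42 in BBm against 5.92 in Lm and 5.54 in LLm, with 7.15 in the parental line. EFEMP1 was higher by 4.06 ± 0.54 (adjusted p = 0.00041), DAPK1 by 3.40 ± 0.39 (adjusted p = 5.54e-05) and CXCR4 by 2.44 ± 0.34 (adjusted p = 0.00056). EREG was lower by 3.92 ± 0.60 (adjusted p = 0.0014), CSF3 by 5.35 ± 0.96 (adjusted p = 0.0057) and SPARC by 5.25 ± 1.17 (adjusted p = 0.028). Of 8374 genes, 79 passed, 49 higher and 30 lower, and 1061 had an unadjusted p under 0.05. The count was 235 under quantile normalization and 137 at the trimmed mean. It was 19 without Bm, 22 without BBm and 25 without LLm. Of 18 named genes past the threshold, 5 passed with any 1 line left out, and the calls of SPARC, ADAMTS1, LOXL1, C4BPB and DLC1 ended without any 1 of Bm, BBm, Lm and LLm (adjusted p from 0.056 to 0.22).

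INHBA, LINC00472, ADAMTS1, LOXL1 and C4BPB were higher on the bone partner side by 2.93 to 3.64, and COL6A1, PPL, PCBP3 and SNED1 lower, from -3.97 to -2.63. DLC1 was lower by 2.76, with 0 of its 2 other probe sets of the same sign. The known bone metastasis genes were higher (camera adjusted p = 6.61e-05, and adjusted p = 0.23 with an estimated correlation), with 2 of 8 past the threshold, CXCR4 and ADAMTS1, and 3 adjusted over the list alone. The known lung metastasis genes were lower (camera adjusted p = 0.00032, and adjusted p = 0.23 with an estimated correlation), with 2 of 17 past the threshold, EREG and SPARC, and 3 adjusted over the list alone. DNA replication genes were lower (camera adjusted p = 0.0025, and adjusted p = 0.83 with an estimated correlation), with 1 of 24, MCM5 at -1.07, past the threshold and 2 adjusted over the list alone. Interferon response genes were higher (camera adjusted p = 0.034, and adjusted p = 0.83 with an estimated correlation), with 0 of 19 past the threshold and 1 adjusted over the list alone. IFIT1, at 2.43 (adjusted p = 0.079), passed without Lm (adjusted p = 0.019), under quantile normalization (adjusted p = 0.045) and with array weights (adjusted p = 0.034). Without LLm the calls ended for DNA replication (adjusted p = 0.93) and interferon response (adjusted p = 0.51), and the latter also under quantile normalization (adjusted p = 0.059).

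BBm and LLm were compared with Bm and Lm to see what fusion changes without mixing partners. TFAP4, at 1.56 ± 0.34, and KHK, at 1.61 ± 0.35, had the smallest p-values (limma adjusted p = 0.65 for both). SPINK1, at -1.70 ± 0.40, PNPLA4, at -1.55 ± 0.38, and DYNC1H1, at -1.25 ± 0.34, were lower and CCR2, at 1.03 ± 0.25 with its other probe set of opposite sign, was higher, none past the threshold. The fall of SPINK1 (-2.90 in BBm, -0.50 in LLm) and PNPLA4 (-2.74 and -0.36) and the rise of CCR2 (1.56 and 0.50) lay mainly in the Bm pair, and the rise of TFAP4 (1.03 and 2.09) and fall of DYNC1H1 (-0.82 and -1.67) more in the Lm pair. Limma called 0 of 8374 genes (1 with the actin ratio as a covariate, NCAPH2, picked after its value was seen), and 268 had an unadjusted p under 0.05. DNA replication genes were higher as a list (camera adjusted p = 2.9e-06, and adjusted p = 0.74 with an estimated correlation), with a median of 0.23 and 0 of 24 past the threshold, also adjusted over the list alone. From Lm to LLm the median was 0.57, also under quantile normalization, and 0.55 at the trimmed mean, with 22 of 24 genes higher. From Bm to BBm it was -0.02 with 10 higher, 0.11 under quantile normalization and 0.09 at the trimmed mean, with 16 higher in each. In BBm against Bm alone the list did not pass under any of these scalings (camera adjusted p = 0.72, 0.36 and 0.62). A test of whether self-fusion changed Bm and Lm differently called 0 genes, with 193 at an unadjusted p under 0.05.

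The position of each line on the bone and lung signatures asked whether hetero-fused lines held both, where 0 is the weak mean and 1 the mean of the metastatic lines. The sample labels already mark the hetero-fused lines for both signatures. They mark Bm, BBm and the bone lines for bone, Lm, LLm and the lung lines for lung, and the others for neither. The positions therefore describe how far the values follow these labels. On the bone signature the hetero-fused lines lay at 0.790 ± 0.041 (SD, n = 5), from 0.735 to 0.840. Lm lay at 0.379 and LLm at 0.370 (2-sided exact permutation p = 0.0952, the smallest that 21 splits allow). The weak lines lay at 0.170 ± 0.205 (SD, n = 6; 2-sided exact permutation p = 0.00433, the smallest that 462 splits allow), with SCP28 at 0.533. The bone lines, each scored with a signature derived without it, lay at 0.791 ± 0.175 (SD, n = 5), Bm at 1.29 and BBm at 1.19. The background was 0.130 in the parental line and 0.175 to 0.340 in the lung lines. With genes taken from the bone and lung lines directly, the bone position was -1.31. These genes were chosen as higher in bone than in lung lines, across array sets, and need not differ between bone and weak lines. The scale, set by bone less weak lines, therefore has no plain reading there, and no conclusion is drawn.

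On the lung signature the hetero-fused lines lay at 0.784 ± 0.016 (SD, n = 5), with Bm at 0.589 and BBm at 0.662 (2-sided exact permutation p = 0.0952, the smallest possible). The weak lines lay at 0.112 ± 0.101 (SD, n = 6; 2-sided exact permutation p = 0.00433, the smallest possible). This signature comes from lines on different array sets, and on both signatures the hetero-fused and weak lines lay on different sets. The difference from the weak lines can therefore not be told apart from the array sets. Of the 431 genes, 96.1% kept their direction in hetero-fused against weak lines, but 68.4% between the partner sides, within the fusion arrays. The lung lines lay at 0.923 ± 0.094 (SD, n = 5), Lm at 0.916 and LLm at 0.855. The parental line lay at 0.213 and the bone lines from -0.025 to 0.361, so Bm and BBm, on the fusion arrays, lay above all bone lines. With the 50 genes of smallest p and with no minimum fold the separation from Bm and BBm was lost (exact permutation p = 0.286 for both), so that from the bone partner side depended on the choice of genes. With BLm-DRUG and its clones averaged, the hetero-fused lines lay at 0.794 on the bone and 0.784 on the lung signature, each with an exact permutation p of 0.333 against the 2 lines of the opposite side and 0.0714 against the weak lines, the smallest possible for 2 lines. On the known lung list alone BLm-FACS lay at 0.922 and BLm-DRUG at 0.918, with the 3 clones from 0.446 to 0.525. The clones lay below the bone lines SCP14 at 0.558 and SCP46 at 0.552, and above the other bone lines, from 0.117 to 0.277. This list therefore did not separate the clones from all bone lines. On the known bone list the weak line SCP28, at 0.710, lay above BLm-DRUG at 0.630 and BLm-DRUG-18 at 0.641. The other hetero-fused lines lay from 0.733 to 0.850 there.

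**Figure D3:**
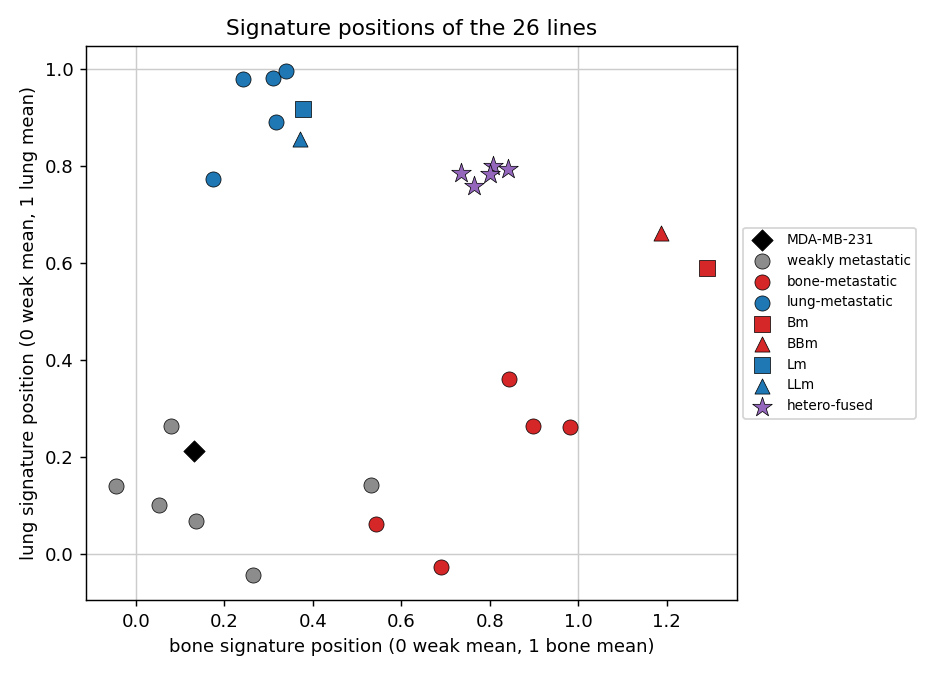
Position of each line on the bone and lung signatures, where 0 is the mean of the weak lines and 1 that of the metastatic lines. The 5 hetero-fused lines lay at 0.790 ± 0.041 on the bone and 0.784 ± 0.016 on the lung signature. The lung signature comes from lines on different array sets, and the hetero-fused and weak lines lay on different sets too.

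The position of the hetero-fused lines between the partners was taken over 652 genes, 390 higher in Bm and 262 higher in Lm, with 0 at LLm and 1 at BBm. It was 0.400 ± 0.071 (SD, n = 5), and its difference from 0.5 had an exact 2-sided sign-flip p = 0.0625, the smallest that 5 lines allow. No p with 5 lines can fall below 0.05, so the difference from 0.5 was not established. The position was 0.483 with a minimum log2 difference of 2 (exact sign-flip p = 0.625) and 0.428 with the centred ratios (exact sign-flip p = 0.438). With genes selected on the self-fused lines it was 0.378 (exact p = 0.125), and with BLm-DRUG and its clones averaged 0.411 (exact p = 0.5, the smallest that 2 lines allow). For genes higher in Bm it was 0.530 ± 0.216 (SD, n = 5), against 0.644 for an average of the linear levels of BBm and LLm. For genes higher in Lm it was 0.232 ± 0.242 (SD, n = 5), against 0.352. BLm-FACS lay at 0.747 for genes higher in Bm and 0.021 for genes higher in Lm, and BLm-DRUG at 0.771 and -0.049. The clones lay at 0.462 and 0.526 for BLm-DRUG-8, 0.349 and 0.378 for BLm-DRUG-12, and 0.320 and 0.282 for BLm-DRUG-18. At the trimmed mean BLm-FACS lay at 0.570 and 0.156, and BLm-DRUG at 0.557 and 0.129. The mean of the hetero-fused lines lay between BBm and LLm in 59.7% of the genes, above both in 22.4% and below both in 17.9%. Of the difference between Bm and Lm in these genes, a share of 0.528 was kept between BBm and LLm.

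**Figure D4:**
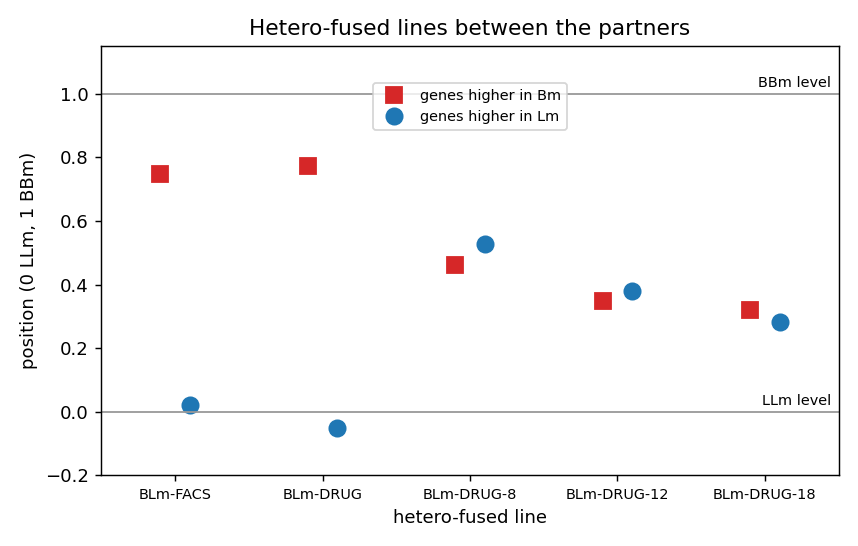
Position of each hetero-fused line between LLm (0) and BBm (1), for genes higher in Bm and genes higher in Lm. BLm-FACS and BLm-DRUG lay at 0.747 and 0.771 for genes higher in Bm and at 0.021 and -0.049 for genes higher in Lm.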

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

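The tests of the 18S ribosomal RNA signal in this part were chosen only after that signal was seen, while the search for single lines apart from their group was planned. Of 257 groups of values searched, 15 (5.84%) had 1 line apart from the rest of its group, and chance gives about 5%, so single cases carry little weight.

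Among the bone lines, DAPK1 was lowest in 1833 at 7.48, with the others from 8.84 to 9.22, and GPRC5C was highest in 1833 at 6.37, with the others from 4.79 to 5.05. DLC1 was highest in SCP20 at 10.32, with the others from 6.87 to 7.79, and IL11 was lowest in SCP20 at 9.84, with the others from 11.01 to 11.27. PNPLA4 was lowest in SCP25 at 8.33, with the others from 8.82 to 8.92. Among the lung lines, SPARC was lowest in 3481 at 6.18, with the others from 11.46 to 11.91, and TNC was highest in 4175 at 9.44, with the others from 8.39 to 8.58. C2orf68 was highest in 4173 at 6.74, with the others from 4.88 to 5.01, and TAP2 was lowest in 4173 at 7.23, with the others from 7.72 to 7.76. Among the weak lines, PPL was lowest in SCP6 at 7.83 and CTSB in SCP6 at 11.62, SPARC was highest in SCP3 at 6.72, and H3-3A, a histone gene whose probe sets can cross-hybridise, was highest in SCP28 at 10.73. Among the hetero-fused lines, CXCR4 was highest in BLm-FACS at 8.77, with the others from 8.42 to 8.52, and the 18S ribosomal RNA signal was highest in BLm-DRUG-8 at 6.45, with the others from 4.55 to 4.81.

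The 18S ribosomal RNA probe sets, which the comparisons did not use, had a mean log2 signal of 12.10 on the 5 arrays of the lung lines and 4.38 to 6.76 on the other 21. If the lung-metastatic type raised this signal, Lm and LLm should share it, but their mean was 5.36, which argues against the type alone. If the 5 arrays formed a set of their own, their hybridisation controls should lie apart, and 0 of the 21 other arrays had controls within their range. The array sets were drawn from these same controls, so this test cannot tell a difference in sample preparation from another cause. The labels give no preparation date, so what differed stays open.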

How the results depend on the processing

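Among the settings below, the trimmed mean, the centred ratios, 3 array sets, the array median, the actin ratio, the subsets of hetero-fused lines, the positions with BLm-DRUG and its clones averaged and the removal of 1833 with SCP46 were chosen only after the data were seen. Where a result moved and no cause is given, the cause was not tested.

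For bone against weak lines, 160 genes became 60 with the centred ratios, 18 with only the groups compared, 298 with the fusion arrays as a covariate, 255 with the actin ratio as one and 88 without 1833 and SCP46. Only the groups compared gave 2654 genes for lung against weak lines, 3376 for hetero-fused against weak and 1907 for bone against lung. The changes themselves are the same in both fits of bone against weak lines, with a median log2 change of -0.048 over all genes in each. The fall to 18 therefore lies in the estimated spread and its residual degrees of freedom. Which of these made it was not tested. The 160 calls thus depend on a spread shared with the other groups. For lung against weak lines, 2593 became 3 with 3 array sets and 605 with the array median. For bone against lung lines, 2341 became 90 and 1257. For hetero-fused against weak lines, 3335 became 41 with the fusion arrays, 0 with 3 array sets, 706 with the array median, 1574 with BLm-DRUG and its clones averaged and 1662 with BLm-FACS and BLm-DRUG alone. Array sets overlap with line types, so these fits rest on fewer lines and also take out any difference between sets. Which of these made the loss was not tested. With 3 array sets the lung lines do not enter the difference from weak or bone lines.

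For hetero-fused lines against the bone partner side, 45 became 105 with quantile normalization, 174 with array weights, 71 with only the groups compared, 3 with BLm-DRUG and its clones averaged, 76 with the array median and 105 with the actin ratio. Against the lung partner side, 4 became 89 with quantile normalization, 12 with the mean of probe sets, 24 with either pseudocount, 31 at the trimmed mean, 12 with centred ratios, 137 with array weights and 32 with only the groups compared. It became 0 with BLm-DRUG and its clones averaged, 1 with BLm-FACS and BLm-DRUG alone, 14 with the clones alone, 21 with each partner joined to its self-fused line, 46 with the array median and 63 with the actin ratio. For bone against lung partner side, 79 became 235 with quantile normalization, 137 at the trimmed mean, 48 with centred ratios, 222 with array weights, 131 with the array median and 156 with the actin ratio. Self-fused against unfused lines stayed at 0 by limma in all settings but the actin ratio, with 1. Only the groups compared could not be fitted for the last 2, which leave no residual degrees of freedom.

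The bone position of 0.790 became 0.849 at the trimmed mean, 0.697 with centred ratios and 0.724 with the known list. It became -1.31 with genes from bone against lung lines, for which the scale has no plain reading. The lung position of 0.784 became 0.745 with quantile normalization, 0.814 at the trimmed mean, 0.757 with centred ratios, 0.840 with the top 50 genes, 0.862 with no minimum fold, 0.451 with genes from bone against lung lines and 0.654 with the known list. The position between partners became 0.483 with a minimum difference of 2 (exact sign-flip p from 0.0625 to 0.625). The averaged positions stayed. The 41 list calls became 26 with quantile normalization and 2 with an estimated correlation.

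Without 1 line the counts ran from 70 (SCP14) to 402 (SCP46) for bone against weak lines, 2033 to 2712 for lung against weak, 1866 to 2369 for bone against lung and 2864 to 3374 for hetero-fused against weak. They ran from 11 (Bm) to 44 against the bone partner side, 0 (LLm) to 7 (Lm) against the lung partner side, 19 (Bm) to 54 between the sides and 0 to 0 for self-fused lines. The positions ran from 0.777 to 0.803 for bone, 0.780 to 0.791 for lung and 0.377 to 0.424 between partners. A group left with 1 line was assumed to vary like the others.

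Named genes turned direction with 3 array sets in lung against weak lines (TNC -0.31, DOCK2 0.69, C2orf68 0.54, RPL32 0.18 and NDUFS1 0.011), bone against lung lines (C2orf68 -0.21 and RPL14 -0.070) and hetero-fused against weak lines (IL1B -0.47, and -0.084 with the fusion arrays). FSCN1 turned to -0.37 with the array median in hetero-fused against weak lines, and the cause was not tested. CCR2 turned to -1.35 with centred ratios in self-fused lines. That setting takes the probe set with the largest SD, and the other probe set of CCR2 had the opposite sign. With 1 line left out, 1556 values for named genes stayed on their side of the threshold, 110 lost their call, 9 gained one and 0 turned direction. With quantile normalization 176 stayed, 4 lost and 3 gained a call, and at the trimmed mean 183 stayed. Arrays with signal near background limit low-level genes, of which 3589 were not tested.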

Other observations

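All tests of the ribosomal protein genes in this part, that of a mixture of partner cells and the count of cholesterol synthesis genes above both partner sides were chosen only after the result was seen, as was the fit of other splits with the array median. The counts of other splits of the lines and the test of scaling for the hetero-fused lines were planned before.

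INSIG1 lay above both partner sides in the hetero-fused lines, by 2.38 against Bm with BBm and by 1.66 against Lm with LLm, only the former past the threshold. Of 15 cholesterol synthesis genes, 14 had a mean above each partner side under all 3 scalings, against 24.4% of the 8374 genes. The sides share the same hetero-fused lines, so they do not support each other independently. The list had a median of -0.18 in self-fused against unfused partner lines. Against lines of their own type on other arrays, Bm with BBm differed from the bone lines in 1224 genes, 209 higher and 1015 lower. Lm with LLm differed from the lung lines in 78 genes, 18 higher and 60 lower.

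Ribosomal protein genes were lower in the lung and hetero-fused lines than in the weak lines. If strong metastatic ability lowered them, they should be as much lower in the bone lines, but their median less that of all genes was -0.107 there, which argues against it. If array sets differ in these genes, Bm with BBm should lie below the bone lines, of the same type on other arrays, and the difference was -0.588, which is consistent with a difference between sets. Quantile normalization left -0.112 in the hetero-fused against weak lines and as much in Bm with BBm against the bone lines, and because it changes all genes of an array together it does not separate scaling from the sets. Which step differed between the sets, and whether cell growth did, stays open.

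Over the genes chosen from Bm and Lm, BLm-FACS and BLm-DRUG lay further toward the higher partner in both directions than the clones did. Their mean position was 0.759 against 0.377 for genes higher in Bm and -0.014 against 0.395 for genes higher in Lm, with an exact permutation p of 0.2 for each, the smallest that 2 against 3 lines allow. Under quantile normalization the smallest difference between a clone and these 2 lines for genes higher in Lm was 0.194, which argues against scaling as the only cause. Its size did depend on the scaling, at 0.261 before and 0.156 at the trimmed mean. With genes chosen from BBm and LLm, the order did not hold at the trimmed mean for genes higher in BBm. There BLm-DRUG lay at 0.330 and BLm-FACS at 0.416, with BLm-DRUG-12 at 0.402. Unfused partner cells in these cultures could hold both levels, although the names give BLm-FACS as sorted and BLm-DRUG as drug-selected, steps that should remove such cells. How far they did was not measured. The smallest excess of an unfused mixture over the observed position was 0.167, but -0.075 at the trimmed mean, so such a mixture and fused cells cannot be told apart because the excess turns with the scaling.

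Other splits of the same lines into groups of the same sizes were fitted, 100 for each comparison with the real one included. For bone against weak lines, 6 of 100 gave at least the 160 genes of the real split, and the highest other gave 425, so chance is not excluded. That split parted arrays with a median signal of 129 to 142 from those with 115 to 129, so it follows the array median. Whether that is technical or the lines' own expression was not tested. With the array median as a covariate the real split gave 167 genes, 2 of 100 were as large, and the highest other gave 289. For the 3 further comparisons, 1 of 100 splits, the real one, was as large, the smallest share that 100 splits allow. The real split also parts the array sets there, so line type and array set were tested together. For hetero-fused lines the splits also counted BLm-DRUG and its clones as separate lines. Lung against weak lines gave 2593 genes and the highest other split 1195, bone against lung lines 2341 and 467, and hetero-fused against weak lines 3335 and 2210.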
